A study of Drosophila melanogaster with 4 samples.

How the data were processed

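H3K36me3 was measured by ChIP-seq in head nuclei of adult Oregon-R flies, a laboratory wild-type strain. Per the labels' protocols, flies came from population cages, heads were collected with sieves, chromatin was crosslinked with formaldehyde and sonicated, and the immunoprecipitated DNA was recovered from protein A beads. The labels give 2 precipitated libraries and 2 input libraries and name an input library for each replicate list. They do not say that the replicates came from separate cultures or collections, so an SD with n = 2 measures only the spread between these libraries, which may be technical. Other SDs are over clusters or arms, as stated beside them. The p-values rest on shifted lists, or on windows, clusters or arms within these libraries, and none measures the spread between libraries or flies. The stage is given as mixed adult, and the share of each sex is not given in the sources used here.

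The authors deposited lists of enriched clusters in general feature format version 3. Each cluster has a first and last base, counted from 1, and a score. Per the file headers, positions are on release 5 of the fly genome. The enrichment score of each cluster is the authors' own value, deposited with the list, and its scale and log base are not given in the sources used here. It was used to describe, rank and filter clusters within a list, and to correlate the replicates. Per the submitters' processing notes Bowtie 0.12.7 was used, with no role stated. The cluster caller, its threshold, the handling of repeated reads, the way in which replicates were combined and the read depth are likewise not given in the sources used here. Depth is therefore unknown and no counting interval was computed for any cluster.

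There were 3 lists, for replicate 1, replicate 2 and the replicate set. In the combined list 1 region was marked as depleted rather than enriched, and it was kept out of all counts of enriched clusters. The input libraries had no list analysed here, so enrichment over input enters only through the authors' calls.

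The only gene table used here was on release 6 of the fly genome. Coordinates were not converted between releases, so no cluster was assigned to a gene. For this reason 5 planned results were not run, namely marked genes, position within genes, exons against introns, gene length and marking, and the tests of gene lists. The rule for named items, fixed before the data were examined, then called for positions only. It took the 5 highest-scoring and the 5 widest clusters of the combined list and the 5 highest-scoring clusters found in each replicate alone.

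Overlap of the replicates, covered length, X against the autosomes and the correlation of scores were also fixed before the data were examined. Overlap required at least 1 bp. It was compared with 1000 random circular shifts of a list within each sequence, which keep the widths and spacing of clusters, in a one-sided permutation test. Covered length was the summed width of the clusters of a list, as a mean and SD of the replicates. X was compared with 2L, 2R, 3L and 3R over windows of 1 Mb of the mean of the replicates, with 100000 permutations, two-sided, and a 95% interval from 10000 bootstrap draws. Windows and clusters are not replicates, and neighbouring windows are alike, so these p-values describe the libraries at hand.

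The comparisons of chromosome 4 and of the heterochromatic sequences with the long arms, of pairs of arms, and of scores and widths by class of sequence were added after the lists had been seen. The same holds for the shares of clusters on U and the heterochromatic sequences among those found in a single list, and for scores on X by width, for which a score limit of 0.8 and the width classes were chosen after the distribution of scores had been seen. Windows of 200 kb were used for chromosome 4. The last window of a sequence was kept if it had at least 50% of the full size and left out otherwise. Adjusted p-values are by the Benjamini-Hochberg method within families of 16 tests on classes of sequence, 20 on X scores, 10 on pairs of arms and 3 on clusters found in a single list, and the threshold was 0.05.

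The tests were first run on simulated lists. With an unrelated list, placed at random, the shift test called 5% of 100 simulations. With a list made only of a random 30% of the other list's own clusters it called 100%. The unrelated lists lacked the close spacing of the real clusters, so the 5% was not shown for lists spaced like these. The test over windows called a raised X in 4% of 100 simulations with no rise, 33% with 3 points added and 99% with 6 points added. The windows were shuffled in these simulations, so the likeness of neighbouring windows was not included.

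Alternatives were a reciprocal overlap of 50% or 50% of the cluster in question, the upper 50% of each list by score, the long arms and chromosome 4 only, each replicate alone, the combined list, windows of 200 kb or 100 kb, log scores, medians, and clusters of 3 kb or wider. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.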

Results

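Trimethylation of lysine 36 of histone H3 (H3K36me3), a histone mark of the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from the heads of wild-type Oregon-R Drosophila melanogaster adults. The 4 libraries fell into 2 groups, 2 from chromatin precipitated with an antibody against H3K36me3 and 2 from input chromatin, and the labels named an input library for each replicate list of clusters. What was compared here were the authors' lists of enriched clusters, with a list for each precipitated library and a combined list for the replicate set. Read depth was unknown from these lists, and all positions are on release 5 of the fly genome.

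H3K36me3 clusters covered about the same length in both replicates. Replicate 1 had 3890 clusters over 24.4 Mb and replicate 2 had 3923 clusters over 24.4 Mb, a mean covered length of 24.4 Mb ± 0.0381 (SD, n = 2). This was 14.5% ± 0.0226 (SD, n = 2) of all assembled sequence, with all unplaced scaffolds included. It was 19.7% ± 0.0279 (SD, n = 2) of the 5 long chromosome arms. The combined list had 4026 enriched clusters over 25.7 Mb. Clusters were broad, with a median width of 4.90 kb in each replicate and 4.96 kb in the combined list. The widest reached 40.6 kb in each replicate, and 65 clusters of replicate 1, 58 of replicate 2 and 83 of the combined list were 20 kb or wider.

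Wider clusters had higher values of the authors' enrichment score, whose scale is not given in the sources used here. Across clusters, which are not independent replicates, Spearman's rho between width and score was 0.743 in replicate 1 and 0.738 in replicate 2. The median score was 0.555 in replicate 1 and 0.509 in replicate 2 for clusters narrower than 2 kb. It was 1.18 and 1.16 from 2 to 4 kb, 1.82 in both replicates from 4 to 8 kb, 2.03 and 1.99 from 8 to 16 kb, and 2.16 and 2.11 above that.

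The 5 highest-scoring clusters of the combined list lay on U, 3L, 2R and 3R. The highest was on U, the collection of scaffolds not placed on a chromosome, at 6383936 to 6389126, with a score of 2.77 ± 0.134 (SD, n = 2) in the replicates. The next were 3L 6736662 to 6745448 with 2.73 ± 0.0169 (SD, n = 2), 2R 5453238 to 5464862 with 2.74 ± 0.0207 (SD, n = 2) and 3R 20060790 to 20084848 with 2.69 ± 0.0036 (SD, n = 2). The fifth was 2R 19411088 to 19417464 with 2.66 ± 0.0595 (SD, n = 2). No gene is named for any cluster, because no annotation of release 5 was used here.

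Of the 5 widest clusters of the combined list, 3 were on X. They spanned X 15607346 to 15650448 (43.1 kb), X 1750640 to 1791386 (40.7 kb) and X 6699188 to 6737268 (38.1 kb). The remaining ones were 2L 8043382 to 8081330 (37.9 kb) and 3R 7032184 to 7069390 (37.2 kb). The first of these was a single cluster only in the combined list, as it overlapped 3 clusters of replicate 1 and 2 of replicate 2, and the third overlapped 2 and 3. Clusters of 20 kb or wider were not more frequent on X. They made up 9 of 729 X clusters against 53 of 2991 on the autosomal long arms in replicate 1 (Fisher's exact test, two-sided, p = 0.419), and 9 of 725 against 45 of 3033 in replicate 2 (p = 0.730, same exact test).

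Both replicates marked nearly the same places. Of the replicate 1 clusters, 3816 of 3890 (98.1%) overlapped a replicate 2 cluster by at least 1 bp, and 3824 of 3923 (97.5%) did so in the other direction. Random circular shifts of a list within each sequence gave means of 32.2% and 32.1% and highest values of 42.3% and 40.1%. The one-sided permutation p was 0.001 in each direction, the smallest that 1000 shifts can give. The lists shared 23.8 Mb, a Jaccard index of 95.1% against 11.3% after shifting.

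Cluster boundaries lay close together in the replicates. Among 3539 pairs of clusters that overlapped only each other, starts differed by a median of 63 bp and ends by a median of 64 bp. The 95th percentiles were 407 bp and 390 bp, and 1 pair had identical boundaries. Scores of 3816 matched clusters correlated with Pearson's r of 0.962 and Spearman's rho of 0.963, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. This correlation is across clusters, which are not independent replicates.

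The clusters found in a single replicate were few, narrow and low in score. Replicate 1 had 74 of them (1.90% of its list), with a median score of 0.592 against 1.71 for its shared clusters and a median width of 1.63 kb against 4.98 kb. Replicate 2 had 99 (2.52%), with a median score of 0.542 against 1.69 and a median width of 1.62 kb against 5.02 kb. The highest-scoring of replicate 1 were U 7638805 to 7640155 (1.11), X 10856037 to 10858343 (1.08), YHet 339556 to 341431 (1.08), X 7565068 to 7567260 (0.950) and U 6733029 to 6734412 (0.915). Those of replicate 2 were U 8228239 to 8229786 (0.955), X 20091259 to 20092706 (0.923), X 19029252 to 19031252 (0.856), X 15990852 to 15992216 (0.826) and X 3063930 to 3065400 (0.782). The combined list held a cluster at each of these 10 places. U and the heterochromatic sequences held 8 of the 74 (10.8%) against 83 of the 3816 shared clusters (2.18%) in replicate 1 (Fisher's exact test, two-sided, adjusted p = 0.00042 over 3 tests), and 4 of the 99 (4.04%) against 83 of 3824 (2.17%) in replicate 2 (same exact test, adjusted p = 0.28).

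The combined list recovered the replicate clusters and added weak ones. All 3890 clusters of replicate 1 and 3922 of 3923 of replicate 2 were found in it. Of its 4026 clusters, 3657 overlapped both replicates, 66 replicate 1 alone, 96 replicate 2 alone and 207 neither. The 207 had a median width of 1313 bp and a median score of 0.393, with a range from 0.0678 to 2.60. On U and the heterochromatic sequences lay 33 of them (15.9%), against 92 of the other 3819 clusters (2.41%; Fisher's exact test, adjusted p = 2.1e-15). By bases, 92.5% of the combined list lay in both replicates, 2.14% in replicate 1 alone, 2.39% in replicate 2 alone and 2.95% in neither.

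Chromosome 4, a short and largely heterochromatic chromosome that carries active genes, had the highest share of marked sequence. Clusters covered 46.2% ± 0.371 (SD, n = 2) of it, against 19.7% ± 0.0279 (SD, n = 2) of the 5 long arms, a difference of 26.5 percentage points. It had 58.4 and 57.7 clusters per Mb in the replicates against 31.3 and 31.6 on the long arms. Clusters there were also wider, by a mean of 1.57 kb in replicate 1 (permutation test, adjusted p = 0.0047) and 1.81 kb in replicate 2 (adjusted p = 0.0015). Over windows of 200 kb, 7 on chromosome 4 and 596 on the long arms, the mean difference was 27.2 points (95% bootstrap interval 18.0 to 36.5; two-sided permutation p = 1e-05, the smallest possible). This comparison was chosen after the lists had been examined, and windows are not replicates, so p describes these libraries only.

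Mean scores on chromosome 4 were not shown to differ from those on the long arms. The difference was -0.124 in replicate 1 (95% bootstrap interval -0.258 to 0.00755; permutation p = 0.05, adjusted p = 0.073) and -0.0641 in replicate 2 (-0.195 to 0.0611; p = 0.32, adjusted p = 0.42). These tests belong to a family of 16, on score and width of clusters by class of sequence in each replicate, with Benjamini-Hochberg adjustment over all 16. They did not match clusters by width. Median widths on chromosome 4 were 7.51 and 7.35 kb in the replicates, against 4.95 and 4.94 kb on the long arms, and wider clusters had higher scores. Whether clusters on chromosome 4 scored lower at equal width was not tested.

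**Figure D1:**
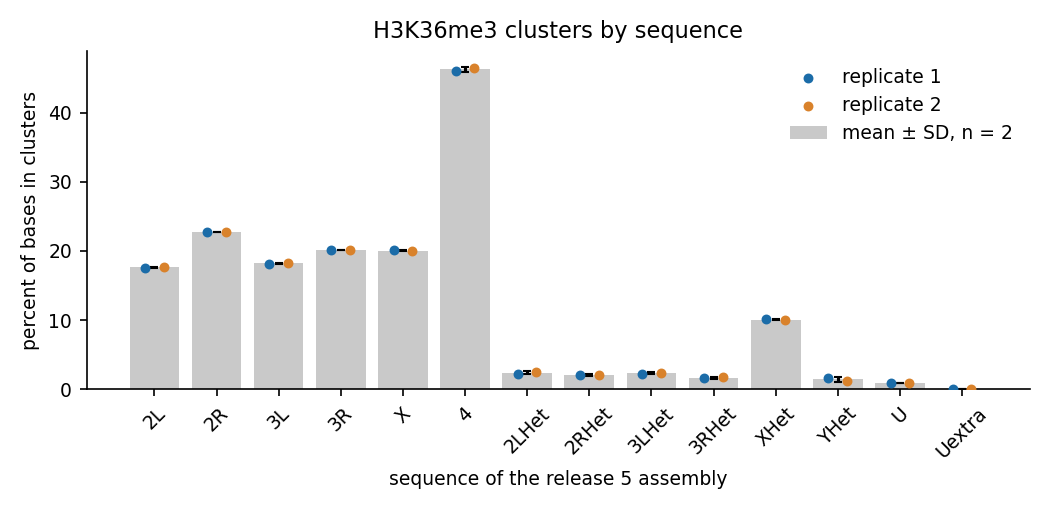
Percent of bases in H3K36me3 clusters (vertical axis) on each sequence of the release 5 assembly (horizontal axis); bars are means and error bars SDs of the 2 replicates, shown as points. Chromosome 4 stands at 46.2%, the long arms lie between 17.7% and 22.8%, and the heterochromatic sequences other than XHet lie at 2.41% or below.

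The long arms ranged from 17.7% ± 0.0806 (SD, n = 2) covered on 2L to 22.8% ± 0.0524 (SD, n = 2) on 2R. Between them were 3L with 18.2% ± 0.0779 (SD, n = 2), X with 20.0% ± 0.0711 (SD, n = 2) and 3R with 20.2% ± 0.00138 (SD, n = 2). The difference between 2L and 2R far exceeded the spread between replicates, but coverage also varied along each arm. Of 10 pairs of arms, tested over windows of 1 Mb by two-sided permutation, 2L against 2R (difference of -5.10 points, p = 0.00935) and 2R against 3L (4.53 points, p = 0.0179) had the lowest p, and both had an adjusted p of 0.0896. None of the 10 passed the adjustment.

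In male flies, X is the chromosome on which the dosage compensation complex reads H3K36me3, so X was set against the autosomes. The share of X covered was 20.0% ± 0.0711 (SD, n = 2), and that of the 4 autosomal long arms was 19.6% ± 0.0509 (SD, n = 2). They differed by 0.378 percentage points. Over windows of 1 Mb, 22 on X and 97 on the autosomes, the mean difference was 0.728 points (95% bootstrap interval -2.31 to 3.86; two-sided permutation p = 0.659), so no difference was detected. In simulated data, a rise of X by 3 points was called in 33% of runs and a rise by 6 points in 99%, so a difference of 3 points could have been missed. The simulated windows were shuffled, so these shares need not hold for real windows, whose neighbours are alike.

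Clusters on X had slightly higher mean scores. In replicate 1 the mean was 1.67 ± 0.522 (SD over 729 clusters) on X and 1.58 ± 0.567 (SD over 2991 clusters) on the autosomal long arms, a difference of 0.0890 (95% bootstrap interval 0.0455 to 0.132; permutation test, adjusted p = 0.00035). In replicate 2 the difference was 0.0701 (0.0276 to 0.113; permutation test, adjusted p = 0.0044). The call rested on the use of means: averaged over the replicates, medians differed by 0.0312 and did not pass the test (permutation p = 0.48, the higher of the replicates), against 0.0796 for means. With clusters of 3 kb or wider only, the means differed by 0.0485 (permutation p = 0.021, the higher of the replicates). Widths were not shown to differ, with adjusted permutation p = 0.48 and 0.66. These tests were added after the lists had been examined.

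The score difference on X passed the adjusted test in both replicates only for clusters under 4 kb. For clusters under 2 kb the mean on X was higher by 0.123 in replicate 1 and 0.135 in replicate 2, each with an adjusted permutation p of 3.3e-05, and from 2 to 4 kb by 0.119 and 0.140, with adjusted p = 0.00046 and 8.6e-05. From 4 to 8 kb the differences were 0.0399 and 0.0314, with adjusted permutation p = 0.14 and 0.22. Clusters of 8 kb or wider differed by 0.0651 in replicate 1 (adjusted permutation p = 0.015) and 0.0337 in replicate 2 (adjusted p = 0.2). These two-sided permutation tests were adjusted over 20 tests on X scores, and whether the difference itself changed with width was not tested.

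**Figure D2:**
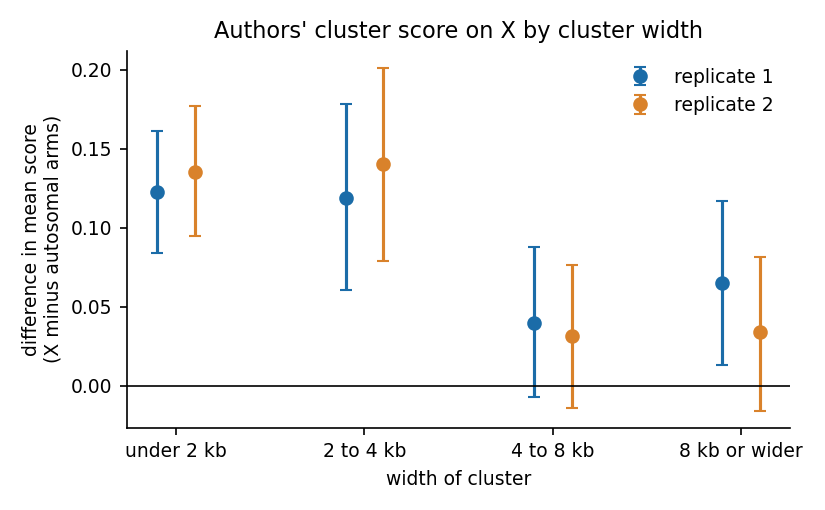
Difference in the mean of the authors' score between clusters on X and on the autosomal long arms (vertical axis, score units whose scale is not given) by width of cluster (horizontal axis); points are replicates and bars 95% bootstrap intervals over clusters. The intervals lie above 0 for both replicates under 4 kb, and in replicate 1 alone at 8 kb or wider.

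Little of the heterochromatic sequence was marked. The 6 sequences of assembled heterochromatin, 9.28 Mb in all, were covered to 2.18% ± 0.0290 (SD, n = 2), with XHet at 10.1% ± 0.0482 (SD, n = 2) on 3 clusters and YHet at 1.42% ± 0.380 (SD, n = 2). U was covered to 0.934% ± 0.0279 (SD, n = 2), and Uextra, 29.0 Mb of further unplaced scaffolds, held 0 clusters in every list. Whether reads were aligned to Uextra at all was not established here, so its 0 clusters need not mean absence of the mark. Clusters on the heterochromatic sequences had lower scores than those on the long arms, by a mean difference of -0.652 in replicate 1 (95% bootstrap interval -0.757 to -0.542) and -0.593 in replicate 2 (-0.703 to -0.475), each with an adjusted p of 8e-05 by permutation. They were narrower too, with differences of -2.84 kb and -2.60 kb and an adjusted p of 0.00028 in each. Those on U were also narrower (-3.40 kb, adjusted permutation p = 0.0004, and -3.29 kb, adjusted p = 0.00075), and their scores were not shown to differ (adjusted p = 0.52 and 0.66). The score tests did not match clusters by width. On U the median width was 2.35 and 2.34 kb in the replicates and the median score 1.45 and 1.43. All clusters of 2 to 4 kb had median scores of 1.18 and 1.16. Scores at equal width were not tested. Read mappability, which limits calls in repeated sequence, was not measured here.

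Coverage varied several-fold along the arms. In 119 windows it ran from 2.58% to 35.5%, with a median of 20.0%. Of these, 117 were full windows of 1 Mb, with a lowest value of 3.55%, and 2 were shorter ends, of 3L and 3R. Ends shorter than 50% of a window were left out. The most covered were 3R from 20 to 21 Mb (35.5% ± 0.371), X from 15 to 16 Mb (34.8% ± 0.245), 3R from 5 to 6 Mb (34.0% ± 0.634), 2R from 3 to 4 Mb (33.4% ± 0.0728) and 2L from 10 to 11 Mb (32.8% ± 0.249), each SD over n = 2. The least covered were the 0.544 Mb end of 3L from 24 Mb (2.58% ± 0.0415), 2L from 14 to 15 Mb (3.55% ± 0.264), 3L from 10 to 11 Mb (5.45% ± 0.0265), 3L from 23 to 24 Mb (6.08% ± 0.402) and 2L from 17 to 18 Mb (6.98% ± 0.206), each SD over n = 2. Replicates differed by a median of 0.207 points per window and by at most 0.897 points, far less than the windows differed from each other.

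**Figure D3:**
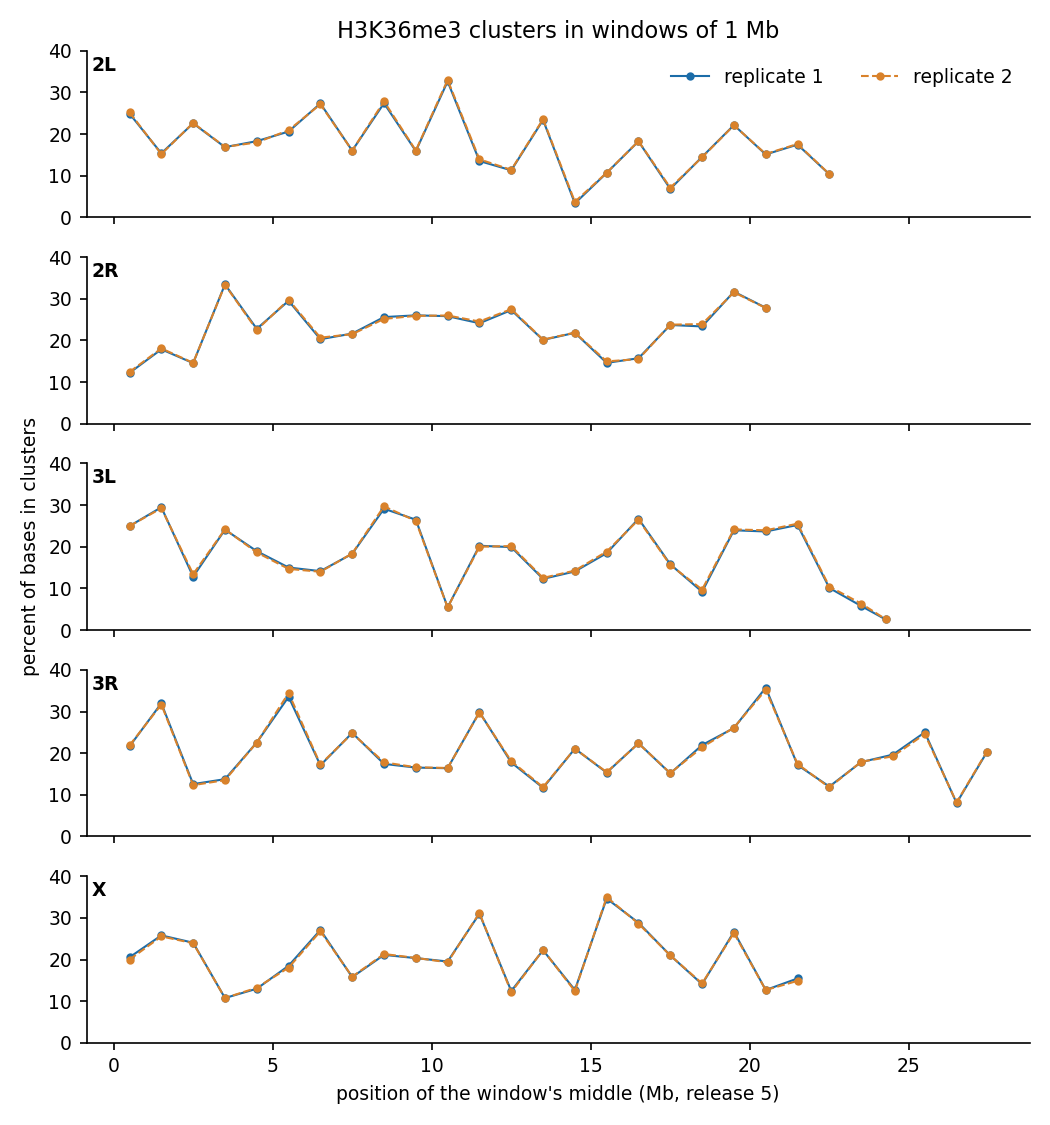
Percent of bases in H3K36me3 clusters (vertical axis) in windows of 1 Mb, or shorter at the ends of 3L and 3R, along the 5 long arms (horizontal axis, position in Mb), with a line for each replicate. The replicate lines lie on top of each other, at most 0.897 points apart, while windows range from 2.58% to 35.5%.

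The longest stretches with no cluster in any list differed in length between the arms. On the long arms they were 2R 15562443 to 16123821 (561 kb), X 20396301 to 20894165 (498 kb), 3L 24071059 to 24531785 (461 kb), 2L 15771427 to 16172124 (401 kb) and 3R 2486258 to 2878706 (392 kb). On chromosome 4 the longest was 714373 to 797606 (83.2 kb).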

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

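The tests in this part were chosen after the patterns they address were seen. For low-scoring calls on chromosome 4, the values that would count for and against were set before the ratio was computed.

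Sequences outside the main comparisons carried clusters, with no input list to compare them with. U held 33 clusters in replicate 1, 31 in replicate 2 and 49 in the combined list, and the heterochromatic sequences held 58, 56 and 76. The highest-scoring cluster of the combined list lay on U. A further region stood out because it was listed as depleted, 2R 1523140 to 1524824 (1685 bp) in the combined list, with a score of -0.00471. Replicate 1 had no cluster there, while replicate 2 had an enriched cluster at 1523145 to 1524608 with a score of 0.342, and this was the 1 replicate cluster missing from the combined list of enriched clusters.

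Chromosome 4 was covered 26.5 percentage points more than the long arms. Low-scoring calls as the whole cause are argued against by the upper 50% of each list by score, in which the ratio of coverage to that of the long arms was 2.43 (2.39 and 2.47 in the replicates). Joining of neighbouring clusters as the whole cause is argued against by the number of clusters per Mb, which was higher on chromosome 4 by a ratio of 1.85. Joining stays open for a part, as clusters there were also wider, by means of 1.57 and 1.81 kb in the replicates. A dense stretch met by chance is argued against by the long arms, where 0 of 2248 stretches of the same length were covered as much (highest 39.0%, at X 15350001 to 16701857). These stretches started every 50 kb and overlapped heavily, so the number of separate stretches was far smaller than 2248. Gene density, mappability, copy number and the input profile of chromosome 4 were not tested and stay open.

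Clusters in a single list were low in score, with median percentiles within their own list of 5.72 and 4.95 for those in a single replicate (mean of the replicates 5.33) and 6.04 for those in the combined list alone. Such percentiles would be seen with calls near the detection limit, and with weaker enrichment being called once the replicates were combined. However, narrow clusters scored low in general. All clusters under 2 kb had median scores of 0.555 in replicate 1, 0.509 in replicate 2 and 0.368 in the combined list. Those found in a single list had 0.592, 0.542 and 0.393. The percentiles therefore cannot tell weak calls apart from narrow ones. Unplaced or heterochromatic sequence is argued against as the main source of the replicate-specific ones, of which 8 of 74 (10.8%) and 4 of 99 (4.04%) lay on U or the heterochromatic sequences (mean of both percentages 7.43). Such sequence was over-represented among those of replicate 1 (2.18% of its shared clusters) and among the combined-only ones (15.9% against 2.41%), so it stays open for a part of both. Repeats within the long arms were not examined, so repeated sequence in general stays open. A shorter minimum width in the combined list is argued against only as the whole source of the added clusters, of which 47.3% (98 of 207) were narrower than any replicate cluster. It stays open for a large part of them. The narrowest cluster had 1001 bp in the combined list, against 1302 and 1305 bp in the replicates, and the added clusters had a median width of 1313 bp. No biological explanation was tested, as both libraries belong to the same group.

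The higher mean score on X may reflect a higher detection limit on that chromosome. Medians differed in the same direction by 0.0312, but did not pass the test (permutation p = 0.48, the higher of the replicates). Clusters under 2 kb scored higher on X by 0.129 on average (0.123 and 0.135 in the replicates), against 0.0494 for clusters of 8 kb or wider. Whether the difference changed with width was not tested. Counts of all clusters showed no loss on X, with 32.5 and 32.3 per Mb in the replicates against 31.0 and 31.4 on the autosomal arms. Clusters under 2 kb made up 46 of 729 on X against 233 of 2991 in replicate 1, and 52 of 725 against 212 of 3033 in replicate 2. X had fewer clusters with scores under 0.8, a limit chosen after the scores were seen, 57 of 729 (7.82%) against 438 of 2991 (14.6%) on the autosomal arms in replicate 1 and 71 of 725 (9.79%) against 467 of 3033 (15.4%) in replicate 2 (Fisher's exact test, adjusted p = 7.8e-06 and 0.00018), though the combined list gave 132 of 747 against 644 of 3072 with an adjusted p of 0.064. The clusters found in a single replicate also scored higher on X, with means of 0.752 against 0.581 in replicate 1 (15 and 50 clusters) and 0.704 against 0.507 in replicate 2 (13 and 80 clusters), each with an adjusted permutation p of 3.3e-05. Those clusters were mostly narrow and low in score, so this largely repeats the comparisons above and is not separate support. Stronger enrichment throughout X stays open, since the 95th percentile of scores was also higher on X (2.41 against 2.35 in replicate 1, 2.35 against 2.31 in replicate 2 and 2.35 against 2.30 in the combined list, with the differences not tested), and since the replicates differed: against it counted a difference in wide clusters of at most 50% of that over all clusters, which replicate 2 met (0.0337, with a bound of 0.0350) and replicate 1 did not (0.0651, with a bound of 0.0445), while in the combined list, which is not independent of them, wide clusters differed by 0.0145 (adjusted permutation p = 0.57) and all clusters by 0.0606. Fewer X chromosomes per nucleus in males, and so fewer reads, would be a candidate source of such a limit, but neither the sex ratio of the flies nor the read depth is given in the sources used here, and neither was tested.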

How the results depend on the processing

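The alternatives for chromosome 4 and for scores on heterochromatic sequences, chromosome 4 and X, and the restriction of covered length to the long arms and chromosome 4, were chosen after seeing the data. Of 42 alternative values, 37 kept their direction and their side of the threshold, or for covered length stayed within the replicate spread, 3 moved, 1 newly passed the threshold, 1 no longer passed it and none was reversed. For covered length, the settings with a replicate left out could only stay within that spread. Each gives the value of the remaining replicate, so they are no test of robustness. The 3 that moved were of covered length, at 24.4 Mb with all clusters. It was 16.7 Mb with the upper 50% of each list by score, 25.7 Mb with the combined list and 24.1 Mb on the long arms and chromosome 4, the first and last by construction, as they leave out clusters. The score difference on chromosome 4 ranged from -0.124 to -0.0641 with each replicate left out, and it reached p = 0.05 by permutation without replicate 2, before adjustment, against 0.32 without replicate 1, for which the cause was not tested. The score difference on X, 0.0796 with means, was 0.0312 with medians and no longer passed (permutation p = 0.48), and it was 0.0485 with clusters of 3 kb or wider, 0.0606 with the combined list and 0.0701 to 0.0890 with each replicate left out, all passing. The cause was not tested. On heterochromatic sequences the score difference ran from -0.851 with medians to -0.583 with clusters of 3 kb or wider, passing in each. Replicate overlap stayed between 94.5% and 98.3% over all settings, X against the autosomes between 0.291 and 0.683 points with no call, and chromosome 4 against the long arms between 19.5 and 28.8 points with p of 0.00013 or lower by permutation. Other settings listed before the data were examined, all based on genes, were not run, for want of a release 5 annotation here. No paired analysis was possible because the input libraries had no list analysed here, so no 2 groups could be compared. Read depth is unknown, so how many weak clusters it kept from being called was not measured.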

Other observations

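The tests in this part were chosen after the lists had been examined, and the clusters singled out here were chosen after their values were seen.

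Clusters lay closer together on the long arms than random placement gives. The median gap between neighbours was 6.06 kb in replicate 1 and 6.03 kb in replicate 2, a mean of 6.05 kb, while the mean gap was 25.7 and 25.4 kb. In 1000 random placements of the same clusters on the same arms, the median gap averaged 17.7 and 17.5 kb and never fell below 16.6 kb (one-sided permutation p = 0.001, the smallest possible). Marked regions may thus lie in groups, perhaps with runs of active genes, but gene positions were not used here and a single wide region called in pieces would give short gaps as well.

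Coverage of the 2 Mb at the centromere-side end of each arm sequence was lower than that of the rest in 4 of 5 long arms. The heterochromatic sequences are kept apart from the arms in this assembly and were not part of these 2 Mb. The differences were -4.05 points on 2L, -8.40 on 2R, -12.7 on 3L and -11.0 on X, and 7.11 on 3R, where the proximal end was covered to 26.8% ± 0.0182 (SD, n = 2) against 19.7% ± 0.00289 (SD, n = 2) for the rest. The mean difference was -5.81 points (SD 7.93 over the 5 arms), with an exact two-sided sign-flip p of 0.1875, where 0.0625 is the smallest that 5 arms can give. With so few arms, a general lowering at these ends cannot be told apart from arm-to-arm variation.

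The 207 clusters found in the combined list alone were mostly weak, but 2 on U had high scores. U 5211932 to 5212932 was 1.001 kb wide and scored 2.60, and U 7584300 to 7586352 was 2.05 kb wide and scored 2.26. Neither replicate list had a cluster at either place.

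Each list had 3 clusters on XHet, and each of those in the combined list overlapped 1 cluster of each replicate. XHet, at 10.1% covered, stood above the other heterochromatic sequences, which lay between 1.42% and 2.41%. Its length is 0.204 Mb, so the value rests on those 3 clusters.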
